A study of Mus musculus with 28 samples.

How the data were processed

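Single cells of mouse embryos at the zygote, 2-cell and 8-cell stages, and mouse embryonic stem cells, were profiled with scDam&T-seq, in which GATC methylation by a Dam fusion protein and polyadenylated RNA are read from one cell. Per the labels, the fusions were Dam-LMNB1 (nuclear lamina), Dam-2E12 (H3K27me3), Dam-CBX1 (H3K9me3) and Dam alone. Embryos were unmodified, came from mothers with Eed deleted in the oocyte (mKO) or their controls, or were injected with Lap2b, Cbx7-Lap2b, Cbx7-Emd or Cbx7-Lbr. The annotation writes the Cbx7 part of these fusions as Cbx7(CD) and Dam-CBX1 in part as Dam-Cbx1(CD), so neither need be the whole protein. Per the labels' protocols, unmodified embryos came from B6CBAF1/J mothers and B6CBAF1/J or CAST/EiJ fathers, and stem cells were 129S1/SvImJ × CAST/EiJ with auxin washed out 6 h before. Sources differ on the fathers of Eed control embryos, which are PWK/PhJ in the growth protocol and JF1 in the titles and the annotation.

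Per the submitters' processing notes, Bowtie2 2.3.3.1, HISAT2 2.1.0 and HTSeq were used and the builds were GRCm38 and mm10, and which tool made which table is not given in the sources used here. The deposited DamID tables hold whole-number unique DamID counts per bin of 100 kb and cell, and the deposited transcript tables hold whole-number counts of unique transcripts per gene and cell. The deposited contact tables hold a 0 or 1 per bin and cell, made by the authors, and how contacts were called is not given in the sources used here. There, 9.94% of the contact bins of a cell had no DamID count (median over 1246 cells), and 102 cells had more contact bins than counts, so a contact call was not a bin with a count. The authors' cell annotation gave construct, stage, condition, embryo and quality filters, and the authors' bin annotation gave mappability and 6 clusters named after LMNB1 and H3K27me3 signal, called K1 to K6 here.

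Each library was divided by construct, stage and condition with the deposited annotation, which gave 43 units from 28 libraries. Of 2773 wells, 77 whole-embryo wells were left out. Cells that passed the submitters' filters were kept, 1232 with DamID counts, 1215 with contacts, 2447 with transcripts and 983 with DamID counts and transcripts. Per cell the DamID total had a median of 30846 (3290 to 561750) and the transcript total one of 25105 (3051 to 310959). The 92 spike-in entries held 0.0311% of transcript counts (0.00325% to 0.132% per unit) and were removed before library sizes were computed. Of 51912 table entries, 51633 matched a gene symbol in the RefSeq table of GRCm38.p6. Of 27236 bins, 23989 were autosomal and mappable and 21712 were clustered. For parental alleles 20804 bins could be seen in every hybrid, 20004 of them autosomal, and 457 of 573 hybrid cells with contacts passed the submitters' allelic filter.

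Cells of a unit were summed for counts and averaged for contacts, since cells are not replicates. Some libraries gave more than 1 unit to a test, by cross or stage, and those units are not fully independent. Nothing in the labels says that libraries came from separate matings, so p-values measure the spread between these libraries or embryos, which may be partly technical. No pair of units of one group agreed within sampling noise (lowest chi-square per degree of freedom 1.12 over 59 DamID pairs and 1.66 over 52 transcript pairs), apart from 1 DamID pair of Dam-CBX1 Eed controls with only 8 testable features (p = 0.0629), so no unit was counted as a copy of another.

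Counts of genes and bins were tested with edgeR 4.0.16 in R 4.3.3 (filterByExpr, TMM, estimateDisp, glmQLFit and glmQLFTest), with Benjamini-Hochberg adjustment and a threshold of 0.05. The stage fits used stage alone, with zygote, 2-cell and 8-cell units in 1 fit. The Eed and Cbx7-Lap2b gene fits and the Eed bin fit had library as a block, because both conditions were processed in each library. Deviations of the units of one library correlated with r from 0.363 to 0.671 in the Eed libraries and from 0.386 to 0.776 in the Cbx7-Lap2b libraries, which was above 0.1 in every library, so libraries were taken to pair the units. In Dam-CBX1 Eed library 2 the r of 0.363 lay below that with a unit of another library (0.401). The Cbx7-Lap2b bin fit used treatment alone. DESeq2 1.42.0 was the alternative tool. Gene lists were tested with camera of limma 3.58.1 with its preset correlation of 0.01, and again with an estimated correlation, adjusted over the lists of a comparison.

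Contact frequency per cluster was compared between stages by exact permutation of units. Eed and Cbx7-Lap2b effects were tested by permuting embryos within a library 100000 times, which gives a smallest p of 1e-05, and parental alleles by exact sign-flips over units. All such tests were two-sided, with Benjamini-Hochberg adjustment over the clusters or loci of a family. Similarity of cells was the mean phi coefficient of pairs of contact maps of a unit, and loci used units with at least 5 cells. Construct profiles were log2 ratios of CPM to Dam-only with a pseudocount of 1, which understates changes of low bins. Expression was compared between cells with and without contact for genes with mean CPM of at least 10, bins contacted in 20% to 80% of cells, at least 3 cells in each class and at least 10 cells per unit, against 100 shuffles. Shares of counts carry 95% Wilson intervals, which cover counting error alone. 

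The tests, groups, gene lists, naming rule and other settings were fixed before the data were examined. The 15 lists were major ZGA genes of the 2-cell stage, oocyte and maternal genes, ribosome biogenesis, ribosomal proteins, lineage and pluripotency, noncanonical imprinted, canonical imprinted, Polycomb developmental targets, PRC2 and PRC1, nuclear lamina and envelope, H3K9 methylation, p53 and DNA damage, cumulus and granulosa markers, fibroblast markers and mitochondrial RNA. Zscan4, Usp17l, Tdpoz and several Gm genes have near-identical copies among which reads can be split, so their values are uncertain. The text names, per comparison, the 8 genes with the largest change up and the 8 down among those past the threshold, at or above the median expression and of the same sign in every pair or without overlap between groups. It also names up to 3 called members of each list with the smallest adjusted p, or the 2 most expressed where none was called. Members called when adjusted over the list alone were named in addition, after their values were seen. Eed, Cbx7, Tmpo, Lmnb1, Emd and Lbr are given in every comparison. Some genes that the rule selects are not reported here. For bins it names the 3 largest changes each way, with neighbouring called bins merged, and the 4 Hox clusters and 6 noncanonical imprinted loci.

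Other settings were DESeq2, total counts in place of TMM, no expression filter, no library block, Dam-LMNB1 libraries alone, non-hybrid crosses alone, embryos or libraries as replicates, at least 10000 DamID counts per cell, autosomes with X, shares of counts in place of contacts, correlation of counts thinned to 10000 per cell, a pseudocount of 10, no division by Dam-only, a contact range of 40% to 60%, an unadjusted threshold for genes, and leaving out each library. Units of more than 10 cells, whole-embryo wells, all cells in place of the allelic filter and unmodified-Eed hybrid units, also averaged per library, were added after the data were seen. The edgeR fits were run on simulated counts with 100 genes or bins changed at each of 2 fold sizes. At 4-fold it recovered 90% and 77% of changed genes for the zygote to 2-cell and 2-cell to 8-cell fits (11351 genes), 92% for Eed (10793) and 88% for Cbx7-Lap2b (10757). At 2-fold the shares were 25%, 14%, 56% and 67%. For bins the 4-fold shares were 98% and 99% for the stages (23521 bins), 91% for Eed (23762) and 83% for Cbx7-Lap2b (18912), and the 2-fold shares 66%, 84%, 29% and 40%. The permutation tests of contact frequency called 5.7% (embryos) and 4.7% (units) of 1000 simulations without an effect. The other tests were not simulated.

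Bins of Dam-CBX1 were not tested between Eed genotypes because 1 library alone had cells of both. The embryo test of Cbx7-Lap2b rests on 1 library with both treatments. Contact-frequency results used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and plots matplotlib 3.10.9.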

Results

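Lamina contacts, chromatin marks and transcripts were measured in single cells of mouse preimplantation embryos with scDam&T-seq, which reads adenine methylation left by a Dam fusion protein and messenger RNA from the same cell. Dam-LMNB1, a fusion to the lamina protein lamin B1, marked DNA at the nuclear lamina. Dam-2E12 carried an antibody-derived H3K27me3 binder, Dam-CBX1 followed H3K9me3, and untethered Dam measured accessibility. The samples comprised 28 libraries, which fell into 43 units when each library was split by construct, stage and condition. DamID counts were used for 1232 cells, binary contact calls for 1215 cells and transcripts for 2447 cells, and 983 cells had both DamID counts and transcripts. DamID counts per cell ran from 3290 to 561750 with a median of 30846, and transcripts per cell ran from 3051 to 310959 with a median of 25105. The genome was followed in 100 kb bins on mm10, of which 23989 were autosomal and mappable. The submitters' annotation sorted 21712 of these bins into 6 clusters, here called K1 to K6, with 4623, 3910, 3990, 2141, 2490 and 4558 bins. The deposited sorting is named as made on LMNB1 and H3K27me3, and which samples entered it is not given in the sources used here. It may have used these samples, so the direction of a cluster was not taken as independent evidence.

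The first comparison asked how the lamina-associated genome was rearranged from the zygote through the 2-cell to the 8-cell stage. K2 bins lost lamina contacts between the zygote and the 2-cell stage and regained a part by the 8-cell stage, while K3 and K4 bins moved the other way at the first step. Contact frequency, the percentage of cells of a unit in contact, was averaged over the bins of a cluster for 5 zygote, 7 2-cell and 6 8-cell units. In K2 it fell from 67.0% ± 3.56 (SD, n = 5) in zygotes to 43.6% ± 2.47 (n = 7) at the 2-cell stage and rose to 63.1% ± 9.14 (n = 6) at the 8-cell stage. Units weighed equally, and the 8-cell units included 1 of 1 cell (80.3%) and 1 of 3 cells (53.6%), while the others read 59.6% to 64.6%. Leaving out any 1 library gave a K2 rise of 16.0 to 21.4 points (exact permutation, highest adjusted p = 0.0190). In DamID counts the return was smaller: K2 held 26.3% to 30.5% of the counts of zygote units, 13.9% to 16.0% of 2-cell units and 18.6% to 24.0% of 8-cell units. In K3 contact frequency rose from 24.4% ± 2.21 to 55.6% ± 2.69 and then fell to 46.8% ± 5.01. In K4 it rose from 16.3% ± 1.15 to 40.4% ± 2.40 and stood at 39.0% ± 3.76 at the 8-cell stage. K1, the bins with the most contacts, had 67.2%, 71.1% and 72.2% at the 3 stages.

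The zygote to 2-cell steps of K2, K3 and K4 each had a p of 0.00126 in a two-sided exact permutation test over units, with an adjusted p of 0.00379 over the 12 tests. K5 rose by 8.14 percentage points (exact p = 0.00505, adjusted p = 0.0101) and K6 by 5.73 (exact p = 0.00884, adjusted p = 0.0152), whereas K1 did not pass (exact p = 0.117). From the 2-cell to the 8-cell stage the exact permutation p was 0.000583 for K2 (adjusted p = 0.00379), 0.00233 for K3 (adjusted p = 0.00559) and 0.0210 for K5, which fell by 4.92 (adjusted p = 0.0315). K4 (exact p = 0.439), K6 (exact p = 0.184) and K1 (exact p = 0.731) did not pass at that step. The mean over all bins rose from 35.2% ± 1.52 to 41.8% ± 2.06 at the first step (exact p = 0.00126, adjusted p = 0.00253) and was 43.0% ± 2.98 at the 8-cell stage (exact p = 0.435). Stages lay mostly in separate libraries, so library and stage overlapped. One library held zygotes (2 cells) and 2-cell embryos (8 cells), and inside it K2 read 62.7% and 45.0%, K3 23.3% and 53.4%, and K4 16.6% and 38.1%. Without that library the K6 step was 5.67 (adjusted p = 0.05), and without the 1 cell of the library with uninjected and tethered embryos the K1 step was 5.35 (adjusted p = 0.0148).

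**Figure D1:**
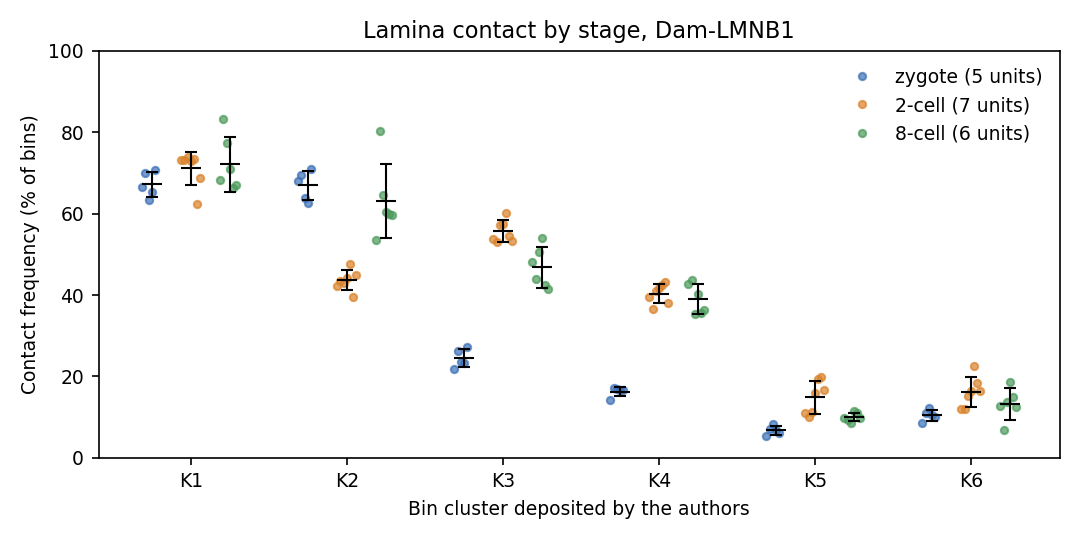
Contact frequency (% of cells in contact, averaged over bins, vertical axis) for clusters K1 to K6 in each Dam-LMNB1 unit of zygotes (5), 2-cell embryos (7) and 8-cell embryos (6), with the mean as a black mark and bars of 1 SD. K2 drops from 67.0% to 43.6% and rises to 63.1%, while K3 goes from 24.4% to 55.6% and 46.8%.

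Single regions showed how large these moves were. On chromosome 7, 23 neighbouring bins from 133300001 to 135600000 rose between the zygote and the 2-cell stage, with a peak log2 change of 2.40 ± 0.35 (SE; 8.50 to 48.4 CPM, counts scaled to library size; edgeR quasi-likelihood adjusted p = 1.43e-10). A stretch of chromosome 12 from 25100001 to 28700000 rose with a peak of 2.38, and chromosome 5 from 127700001 to 128400000 rose as well. On the same chromosome 12, 54 bins from 92300001 to 97700000, all of cluster K2, fell with a peak of -2.59 ± 0.23 (164 to 20.9 CPM). Chromosome 16 from 65200001 to 70200000 fell with a peak of -2.62. The bin from 3000001 to 3100000 on chromosome 9 fell by 3.34 ± 0.26 and then rose by 2.45 at the 8-cell stage. That single bin belongs to no cluster and varied widely among zygote units (70.9 ± 66.4 CPM), so it does not show a move of K1 to K6. From the 2-cell to the 8-cell stage, chromosome 4 from 111800001 to 114500000 (peak 2.14) and chromosome 6 from 89400001 to 90300000 (peak 2.12) rose. Chromosome 17 from 3200001 to 6000000 (peak -1.72), chromosome 13 from 23700001 to 24700000 (peak -1.56) and chromosome 6 from 4400001 to 6500000 (peak -1.55) fell.

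Genome-wide, 12108 of 23521 bins changed between the zygote and the 2-cell stage at an adjusted p under 0.05 in edgeR, 6548 up and 5560 down. DESeq2 gave 9325 up and 3569 down. In K2, 74.1% of bins fell, and in K3 62.6% rose. K4 had 47.5% of bins up, K6 27.6% up, K5 20.9% up, and K1 40.2% down with 13.7% up. From the 2-cell to the 8-cell stage 5539 bins changed, 3111 up and 2428 down, against 2242 up and 1350 down in DESeq2. Of the K2 bins 46.9% rose, 997 of 3987 K3 bins fell, 17.7% of K4 bins rose and 16.9% of K1 bins fell. Without Dam-LMNB1 8-cell library 5 the total at this step was 3503.

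Cells of one unit shared fewer contacts after the first division. The mean phi coefficient between the contact maps of pairs of cells from a unit, which is 1 for identical maps and 0 for unrelated ones, fell from 0.391 ± 0.0510 in 5 zygote units to 0.295 ± 0.0367 in 6 2-cell units (exact permutation p = 0.00649, adjusted p = 0.0130, two-sided). In 5 8-cell units it was 0.298 ± 0.0462 (exact p = 0.894). Without Dam-LMNB1 2-cell library 4 the first difference was -0.0855 (adjusted p = 0.0952), and in non-hybrid crosses alone it was -0.117 (adjusted p = 0.0571), so the call was lost in both.

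Transcripts of the same libraries changed widely at the first step. Among 11351 genes tested in 5 zygote and 6 2-cell units, 4379 rose and 4297 fell (edgeR quasi-likelihood, adjusted p under 0.05). Genes nearly silent in zygotes led the rise: Btbd18 went from 1.24 to 381 ± 61.8 CPM (log2 change 8.43), Selenos from 1.42 ± 1.23 to 466 ± 170 (8.26), Ccdc137 from 0.355 to 116 (8.33), Gm8430 from 0.251 to 104 (8.28), Gm12622 from 0.309 to 80.3 (8.26) and Fam109a from 0.281 to 97.7 (8.72). Fgf4, a growth factor of the early embryo, went from 0.0190 to 99.6 ± 46.0 CPM and Gm12623 from 0.0978 to 193, with too few zygote counts for a fold. Abundant zygotic transcripts led the fall, among them Rgs2, a regulator of G-protein signalling (2055 to 22.8 CPM, -6.51), Fam90a1a (388 to 5.53, -7.62), the homeobox gene Otx1 (141 to 1.38, -6.68), Epsti1 (-6.74), Ifit1bl2 (-6.55), Gpr1 (-6.45), Glrx (-6.16) and Gm813 (-6.04). Inside the library that held both stages, 82.6% of the called genes had the same sign.

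Of the genes this study targets or injects, Eed, a core subunit of the H3K27 methyltransferase PRC2, fell at the first step from 306 to 113 CPM (log2 change -1.40, edgeR adjusted p = 5.95e-05). Lbr, an inner nuclear membrane receptor, rose by 1.80, Emd (emerin) by 1.34 and the Polycomb reader Cbx7 by 1.56, from 4.87 to 15.7 CPM. Tmpo, which encodes Lap2, had 0.39 (adjusted p = 0.180 in edgeR) and Lmnb1 0.16 (adjusted p = 0.648 in edgeR). None of these 6 genes passed from the 2-cell to the 8-cell stage, with log2 changes of 0.13 for Eed, 0.33 for Cbx7, -0.23 for Emd, -0.10 for Lbr, 0.02 for Tmpo and 0.35 for Lmnb1.

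Ribosome genes rose and oocyte genes fell at the first step. Of 68 ribosomal protein genes 66 rose and 1 fell between the zygote and the 2-cell stage, with Rplp1 at 5.21 and Rpl26 at 4.63 (camera adjusted p = 3.25e-11; adjusted p = 0.544 with an estimated correlation). Of 28 ribosome biogenesis genes 25 rose and none of the others fell, among them Nop2 (5.58) and Mybbp1a (4.52; camera adjusted p = 7.52e-07; adjusted p = 0.544 with an estimated correlation). Of 38 oocyte and maternal-effect genes 35 fell and 0 rose, with Ooep at -5.51, Nobox at -5.06 and Zar1 at -4.91 (camera adjusted p = 1.27e-08; adjusted p = 0.544 with an estimated correlation). Of 16 genes of the major wave of zygotic genome activation (ZGA) 11 rose and 2 fell, with Tdpoz1 at 7.04 and Obox3 at 5.19 (camera adjusted p = 0.0667). Several members of that list belong to families of near-identical copies whose reads cannot be fully separated. Of 12 noncanonical imprinted genes, silenced on the maternal allele by H3K27me3, 10 rose and 1 fell, with Tle3 at 5.30 and Jade1 at 5.17 (camera adjusted p = 0.0485; adjusted p = 0.544 with an estimated correlation).

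The other lists split at the first step. Lineage and pluripotency genes had 13 up and 5 down of 24, with Sox21 at 7.22 and Tead4 at 6.56 (camera adjusted p = 0.331). Canonical imprinted genes had 8 up and 6 down of 16 (Igf2r 3.25), Polycomb developmental targets 4 up and 6 down of 12 (Foxa1 3.94, Fgf8 -3.67), and PRC2 and PRC1 genes 5 up and 12 down of 23 (Pcgf5 4.22, Kdm6a -1.75). Lamina and nuclear envelope genes had 7 up and 4 down of 17 (Lemd3 6.60), H3K9 methylation genes 7 up and 9 down of 19 (Suv39h1 6.39), p53 and DNA damage genes 7 up and 4 down of 15 (Bbc3 7.58) and mitochondrial RNAs 12 up and 0 down of 15 (mt-Nd4 1.49). Of 4 cumulus and granulosa markers 2 rose and 2 fell, Amhr2 from 0.159 to 62.4 CPM and Cyp19a1 from 23.6 to 1.29 CPM. Of 2 fibroblast markers Sparc rose, from 1.17 to 6.83 CPM. Counts adjusted over the list alone equalled those over all genes for every list at this step.

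From the 2-cell to the 8-cell stage 2959 genes rose and 3607 fell of the 11351. Gata6, a primitive endoderm factor, rose to 893 CPM (log2 change 5.92), the gluconeogenic enzyme gene Fbp2 from 1.42 to 170 (6.06) and Smpdl3a from 0.941 to 145 (6.43), with Vnn1 (6.24), Reep1 (6.06), Acadl (5.68) and Lasp1 (5.58) also among the largest rises. Omt2b fell from 2278 to 26.9 (-6.07), and B020004C17Rik (-6.10), Omt2a (-6.06) and Grm2 (-5.97) fell likewise. Tcl1b1 went from 291 to 0.968 CPM, with 1 of 5 8-cell units above 0, Bnc2 from 27.5 to 0.161 and Prrg1 from 35.8 to 0.304, with too few 8-cell counts for a fold, as was the case for Hmgcll1. The balance between up and down depended on 1 library: without Dam-LMNB1 8-cell library 5, edgeR gave 1654 up and 4729 down. DESeq2 gave 2597 up and 4293 down, and the median change of all genes was -0.18 in edgeR.

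Ribosomal protein genes rose further, 64 of 68 with none down and 66 when adjusted over the list alone, with Rpl5 at 2.86 and Rpl4 at 2.73 (camera adjusted p = 2.98e-15; adjusted p = 0.382 with an estimated correlation). ZGA genes fell, 12 of 16 with 0 up, led by Obox3 (-5.70) and Tcstv1 (-3.79; camera adjusted p = 0.000912; adjusted p = 0.382 with an estimated correlation). Of the oocyte genes 32 of 38 fell and 3 rose, with Kit at -3.80 and Oosp1 at -3.84 down and Khdc3 at 3.87 up (camera adjusted p = 6.99e-06; adjusted p = 0.382 with an estimated correlation). Of 24 lineage genes 14 rose and 7 fell, and 15 rose when adjusted over the list alone, with Tdgf1 at 4.08 and the trophectoderm factor Gata3 at 3.12 (camera adjusted p = 0.0261; adjusted p = 0.439 with an estimated correlation). Noncanonical imprinted genes had 6 up and 0 down of 12, with Rbms1 at 4.65 and Xist at 4.29 (camera adjusted p = 0.00444; adjusted p = 0.382 with an estimated correlation). Ribosome biogenesis genes had 8 up and 2 down of 28 (Npm1 1.65; camera adjusted p = 0.125). Canonical imprinted genes had 5 up and 4 down of 16 (Mest -2.47), Polycomb targets 3 up and 5 down of 12 (Hoxa7 -4.60), PRC2 and PRC1 genes 6 up and 7 down of 23 (Jarid2 2.64, Bmi1 -3.64), lamina genes 3 up and 4 down of 17 (Lmnb2 3.75) and H3K9 genes 3 up and 6 down of 19 (Suv39h2 -2.72). The p53 list had 5 up, or 6 adjusted over the list alone, and 6 down of 15 (Perp 5.65), mitochondrial RNAs 2 up and 1 down of 15 (mt-Nd3 1.72) and cumulus markers 2 up and 1 down of 4 (Col4a1 2.47). Neither of the 2 fibroblast markers passed (Fn1 -0.72, Sparc -0.90) in edgeR.

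The next comparison asked whether the maternal and paternal genomes contacted the lamina differently, in hybrid embryos whose parental alleles were told apart by strain variants. Across 11 units K2 was contacted in 40.1% ± 13.9 of cells on the maternal and 51.6% ± 10.2 on the paternal genome, and the paternal value was higher in 9 of 11 units. K4 read 25.1% and 36.0%, with the paternal value higher in 8 of 11. Neither passed after adjustment (two-sided exact sign-flip p = 0.0176, adjusted p = 0.123 for K2; exact p = 0.0391, adjusted p = 0.137 for K4). The 11 units included Eed knockouts and embryonic stem cells. In the 7 units of embryos with unmodified Eed, a selection made after the data were seen that pools zygotes, 2-cell embryos and 3 Eed control units, K2 read 30.9% ± 2.94 maternal and 49.8% ± 9.43 paternal, K4 18.1% ± 6.14 and 38.4% ± 12.6, and K5 was higher by 8.94 points on the paternal genome. Each of the 3 was higher on the paternal genome in 7 of 7 units (exact p = 0.0156, the smallest possible; adjusted p = 0.0365). These units came from 6 libraries, and averaged per library the call was lost (6 of 6 libraries, exact p = 0.0312, the smallest possible; adjusted p = 0.0729), with an excess of 18.3 ± 11.2 in K2, 20.2 ± 8.60 in K4 and 8.84 ± 3.70 in K5. The excess differed by stage and cross, without a test. In K2 it was 29.1 and 34.7 in the zygote units, 15.4 and 25.5 in unmodified 2-cell units and 4.87 to 12.9 in Eed controls. In K4 it was 9.11 and 11.7, 32.9 and 36.7, and 16.3 to 18.0. K1 was higher on the paternal genome in zygotes (10.9 and 16.3) and lower in each 2-cell unit (-15.4 to -2.77). In the stem cells (242 cells) the paternal excess was 1.87 points in K2 and 1.49 in K4, without a test.

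The constructs were then set against each other in unmodified 2-cell embryos, to see which marks lay in the lamina-contacting parts. H3K27me3 binding was enriched over Dam-only in K2, with a mean log2 ratio of 0.90, and in K4, with 0.41, and lay below it in K3 (-0.59) and K6 (-0.51). The values for K1 and K5 were 0.04 and -0.17. Dam-CBX1 was also highest in K2 (0.69) and K4 (0.31), and low in K1 (-0.36). Lamin B1 was highest in K1 (0.85), followed by K2 (0.37), K3 (0.22) and K4 (0.00), and low in K5 (-1.12) and K6 (-1.03). The sorting is named as made on LMNB1 and H3K27me3. The H3K27me3 and lamin B1 values by cluster may therefore restate it and are not independent evidence. Across 23989 bins, which are not independent replicates, Dam-2E12 and Dam-CBX1 correlated most (Pearson r = 0.473, Spearman rho = 0.401), then Dam-LMNB1 and Dam-2E12 (r = 0.284, rho = 0.275), and Dam-LMNB1 and Dam-CBX1 least (r = 0.112, rho = 0.0864). The profiles summed 120, 24, 37 and 40 cells for Dam-LMNB1, Dam-2E12, Dam-CBX1 and Dam-only. Without division by Dam-only the rank correlation of Dam-LMNB1 was negative with both marks, at -0.135 with Dam-2E12 and -0.342 with Dam-CBX1.

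The Eed maternal knockout asked whether H3K27me3 inherited from the oocyte shapes lamina contacts at the 2-cell stage. Eed was deleted in oocytes with Gdf9-Cre (mKO), and hybrid embryos of mKO and control mothers were read in the same 3 Dam-LMNB1 libraries, 61 mKO and 80 control embryos. K2 bins gained contacts, from 43.5% ± 5.62 in controls to 61.5% ± 7.90 in mKO embryos, a change of 18.2 points within libraries, and K4 bins rose by 4.89, from 37.8% ± 4.63 to 44.4% ± 6.59. K3 fell by 15.1 (55.8% to 42.9%), K6 fell by 15.4 (29.6% to 16.6%) and K5 fell by 8.10 (23.1% to 17.0%). These 5 changes each had p = 1e-05 (adjusted p = 1.2e-05), the smallest value the two-sided permutation of embryos within libraries could give, while K1 did not pass (2.07 points, permutation p = 0.0607). Unmodified 2-cell units of other crosses read 43.6% in K2, 55.6% in K3 and 40.4% in K4. In K5 and K6 they read 14.9% ± 4.09 and 16.2% ± 3.65, nearer to the mKO embryos than to the controls. The K5 and K6 falls thus started from controls above unmodified embryos and cannot be told apart from raised values in these controls. The K2 gain was 27.4, 16.8 and 18.0 points in libraries 1, 2 and 3. Embryos, not separate cultures, were the replicates here, and with the 3 libraries as replicates p could not go below 0.25. Without library 3 the K1 change was 4.18 (adjusted p = 0.000516).

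Separating the parental alleles showed opposite moves in K4. On the maternal genome K4 rose from 23.5% ± 4.21 to 42.0% ± 7.67 and on the paternal genome it fell from 40.0% ± 5.71 to 34.8% ± 6.48, over 47 control and 38 mKO embryos (permutation adjusted p = 1.5e-05 and 1e-05). The paternal excess in K4 thus went from 16.6 ± 7.68 points to -7.23 ± 5.86, a change of -23.3 (permutation p = 1e-05, adjusted p = 2e-05), and it stayed between -26.7 and -22.8 without any 1 library. K2 rose on both genomes, by 16.4 points on the maternal and 10.8 on the paternal (permutation adjusted p = 1.5e-05 and 1e-05), and its paternal excess fell by 5.54 (permutation p = 0.00345, adjusted p = 0.00518). The paternal excess fell by 11.4 in K5 and rose by 11.3 in K1 (adjusted p = 2e-05 for both in the permutation test), and K3 (permutation p = 0.0943) and K6 (permutation p = 0.654) did not pass. On the maternal genome K3 fell by 11.5 and K6 by 10.6 (permutation adjusted p = 1.5e-05), and K1 (permutation p = 0.165) and K5 (permutation p = 0.864) did not pass. On the paternal genome K1 rose by 8.89 while K3 fell by 8.65, K4 by 6.96, K5 by 11.1 and K6 by 10.2 (permutation adjusted p = 1e-05). Library 3 held 36 of the control and 26 of the mKO embryos, and without it the maternal K3 (-3.27, adjusted p = 0.659) and K6 (-7.74, 0.474), paternal K2 (10.2, 0.0701), K3 (-7.14, 0.0572), K4 (-7.47, 0.0675) and K6 (-10.2, 0.0942), and K1 paternal excess (4.34, 0.500) changes no longer passed. Sources also name different sires for the genotypes: per the growth protocol control embryos had PWK/PhJ and mKO embryos JF1/MsJ fathers, whereas the annotation gives JF1 for both, and the allelic calls depend on the strain used. If the growth protocol is right, sire strain and genotype overlap in every comparison of mKO with control embryos. That includes the contacts with alleles combined, the bins, the similarity of cells and the transcripts.

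**Figure D2:**
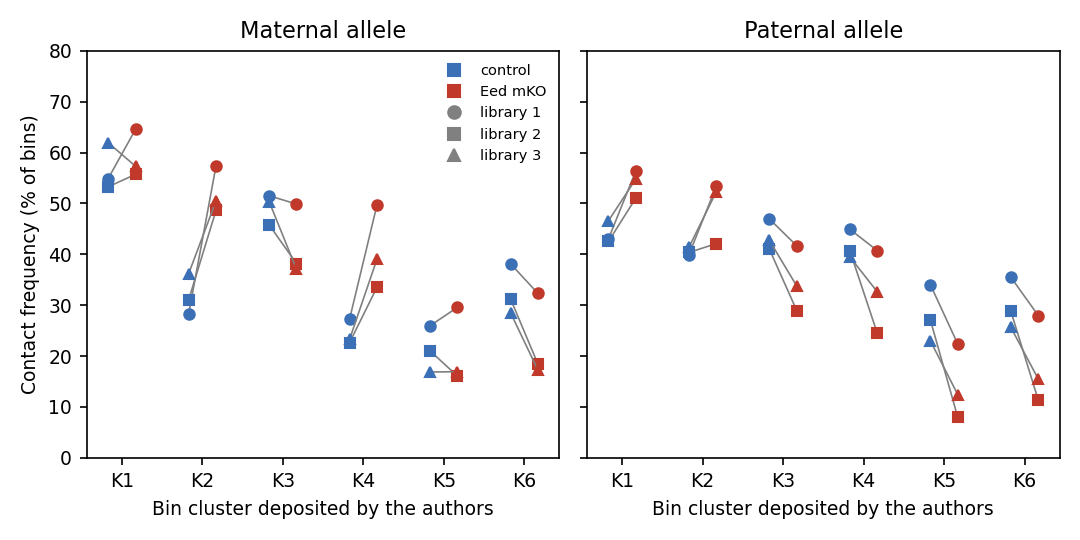
Contact frequency (% of cells in contact, embryo means, vertical axis) on the maternal and paternal genome for clusters K1 to K6 in Eed control (blue) and Eed mKO (red) 2-cell embryos, with lines joining the genotypes of a library (circle, square and triangle for libraries 1, 2 and 3; library 2 has 1 mKO embryo). Maternal K4 is higher in mKO than in control embryos in each library, from 23.5% to 42.0% over all embryos, and paternal K4 is lower, from 40.0% to 34.8%.

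Of 6 loci imprinted by maternal H3K27me3, 3 gained lamina contact on the maternal allele. Sfmbt2 (chromosome 2, 10370440 to 10595253, mm10) was contacted by the maternal allele in 1.42% of control and 73.7% of mKO cells (difference 74.1 within libraries, permutation adjusted p = 5e-05 over 10 loci), while the paternal allele, at 28.8% in mKO cells, did not pass (difference 4.53, permutation adjusted p = 0.642). Smoc1 (chromosome 12, 81026808 to 81186414) rose from 1.60% to 32.7% on the maternal allele (permutation adjusted p = 5e-05) and fell by 25.9 points on the paternal allele (permutation adjusted p = 0.0302). Slc38a4 (chromosome 15, 96994816 to 97055956) rose from 2.13% to 22.1% on the maternal allele (permutation adjusted p = 0.00163). Gab1 (chromosome 8, 80764431 to 80880519) rose from 14.4% to 32.5% with the alleles together (permutation adjusted p = 0.00698), with a maternal adjusted p of 0.113 in the permutation test. Of the 4 Hox clusters, developmental Polycomb targets, 3 had less contact in mKO than in control embryos with the alleles combined. Hoxc (chromosome 15, 102921131 to 103036856) fell by 28.4 points from 44.7% to 19.9% (permutation adjusted p = 0.00025), Hoxb (chromosome 11, 96194316 to 96368254) by 24.1 (permutation adjusted p = 0.000467) and Hoxa (chromosome 6, 52155367 to 52260880) by 16.9 (permutation adjusted p = 0.0232). Controls read 42.5% at Hoxb and 33.8% at Hoxa, and mKO embryos 22.1% at both. Unmodified 2-cell units of other crosses read 29.3% ± 19.7 at Hoxc, 13.8% ± 10.0 at Hoxb and 17.3% ± 10.3 at Hoxa. The Eed controls lay above them at each, so a loss of contact held by unmodified embryos is not shown. Taken singly, the maternal allele fell by 40.1 at Hoxc (permutation adjusted p = 6.67e-05) and the paternal allele by 23.4 at Hoxa (permutation adjusted p = 0.04), while paternal Hoxc (-7.34, 0.577), maternal Hoxa (-1.25, 0.92) and both alleles of Hoxb (maternal -11.2, 0.205; paternal -4.75, 0.642) did not pass. Hoxd (chromosome 2, 74668225 to 74765142) did not pass with the alleles together (-6.91, permutation adjusted p = 0.358) but fell by 21.2 on the paternal allele (permutation adjusted p = 0.04). Jade1 (chromosome 3, 41555734 to 41616864) and Xist (chromosome X, 103460373 to 103483233) passed on neither allele.

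At the level of counts, 2009 of 23762 bins changed in mKO embryos, 1394 up and 615 down (edgeR quasi-likelihood with library as block). In K2 1036 of 3910 bins rose (26.5%) and 0 fell, 11.2% of K4 bins rose, and 6.24% of K3 and 5.89% of K6 bins fell. The strongest gains included chromosome 4 from 76000001 to 76500000 in K2 (peak log2 change 2.31, edgeR adjusted p = 4.00e-05), chromosome 6 from 59900001 to 60100000 (2.40, edgeR adjusted p = 0.00652) and chromosome 2 from 10400001 to 11000000, which overlaps Sfmbt2 (15.9 to 68.2 CPM, edgeR adjusted p = 2.31e-05). The strongest losses included chromosome 17 from 6500001 to 6600000 (-2.43, edgeR adjusted p = 0.0291) and from 30500001 to 31200000 (-1.96, edgeR adjusted p = 0.00562) and chromosome 5 from 149300001 to 150300000 (-1.90, edgeR adjusted p = 0.000338). DESeq2 called 20 bins up and 3 down, and the fit without the library block called 305 up and 63 down. Leaving out library 1, 2 or 3 gave 3406, 798 and 18 bins. The contact maps of cells within a unit resembled each other more in mKO than in control embryos, with a rise in phi of 0.0900 (permutation p = 1e-05, two-sided) and of 0.0183, 0.0988 and 0.0937 in the 3 libraries. Phi was 0.142, 0.125 and 0.191 in the controls and 0.161, 0.224 and 0.284 in the mKO cells of libraries 1 to 3. Unmodified 2-cell units averaged 0.295 ± 0.0367, so both groups lay below them, the controls further in each library. With every cell thinned to 10000 counts the rise in mKO cells, as a correlation of counts, was 0.0430 (permutation p = 1e-05), and library 1, with 4 control cells, turned to -0.00527. Library 2 had 0.0720 from 30 control and 3 mKO cells, and library 3 had 0.0452 from 57 and 51.

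Transcripts of mKO embryos changed at few genes. Eed (ENSMUSG00000030619) itself read 57.5 to 83.2 CPM in the control and 64.6 to 99.0 CPM in the mKO units, a log2 change of 0.23 ± 0.16 (edgeR adjusted p = 0.612), and a 3′ tag outside the deleted part does not check the deletion. Over 5 libraries with both genotypes, 20 genes rose and 9 fell of 10793. Etv6 (ENSMUSG00000030199), a noncanonical imprinted gene, rose to 63.6 CPM (log2 change 1.54 ± 0.26, edgeR adjusted p = 0.0239), and Gpd2 (ENSMUSG00000026827), the mitochondrial glycerol-3-phosphate dehydrogenase, from 58.7 to 162 CPM (1.49 ± 0.17, edgeR adjusted p = 0.00224). Eri1 (1.49), Tpst1 (1.47), Ankmy2 (1.44), Hmgn3 (1.36), Fam46a (1.31) and C130074G19Rik (1.28) also rose in all libraries. Only Gm14350 (-1.20) and Ftl1 (-1.19) met the naming rule among the genes that fell. Hoxd8 (ENSMUSG00000027102) rose from 3.46 to 18.5 CPM (2.45 ± 0.33) and Hoxa7 (ENSMUSG00000038236) fell from 30.4 to 10.2 CPM (-1.60 ± 0.25), and Lncenc1, picked after its values were seen, rose from 0.353 to 12.4 CPM (4.66). Allele-assigned transcripts of mKO embryos were mostly maternal, 60 against 0 paternal for Lncenc1, 79 against 2 for Hoxd8, 556 against 36 for Hmgn3 and 197 against 61 for Gpd2. Whether these were made in the oocyte or by the embryo was not tested.

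The number of called genes depended on the fit: 1291 of the genes had an unadjusted p under 0.05, DESeq2 called 31 up and 22 down, edgeR called 195 without the expression filter and 66 with Dam-LMNB1 libraries alone, and without the library block edgeR called 0, with 256 at an unadjusted p under 0.05. Without Dam-LMNB1 library 3 it called 0 with 930 at an unadjusted p under 0.05, without Dam-LMNB1 library 2 it called 7 and without Dam-CBX1 library 2 it called 5. Embryos as replicates gave 180 calls among 1223 testable genes. Cbx7 (-0.35), Emd (-0.32), Lbr (0.11), Tmpo (-0.13) and Lmnb1 (-0.08) did not pass.

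In mKO embryos no gene list kept a call with an estimated correlation, and few listed genes were called over all genes. Of 9 noncanonical imprinted genes 1 rose over all genes and 5 when adjusted over the list alone, namely Etv6, Rbms1 (2.43), Bbx (0.86), Enc1 (0.83) and Jade1, which went from 87.0 to 151 CPM (0.79 ± 0.16; camera adjusted p = 3.41e-08; adjusted p = 0.315 with an estimated correlation). Gab1 (0.49), Sfmbt2 (0.52), Xist (0.52) and Tle3 (-0.12) of that list did not pass. Of 23 ZGA genes 0 were called over all genes in edgeR but 15 were lower when adjusted over the list alone, led by Zfp352 (-0.67 ± 0.14), Gm8300 (-0.98) and Tcstv1 (-0.97), while of the most expressed members Gm5662 had -0.77 and Sp110 -0.02 (camera adjusted p = 7.22e-18; adjusted p = 0.315 with an estimated correlation). The ZGA median was -1.11 and -1.26 in Dam-CBX1 libraries 1 and 2 and -0.08, -1.05 and -0.33 in Dam-LMNB1 libraries 1 to 3. Of 21 lineage genes 0 were called, and Eomes (-1.40), Elf3 (-0.97) and Zfp42 (-0.85) were lower when adjusted over the list alone, with Klf17 at 0.33 and Klf4 at -0.05 (camera adjusted p = 0.0498; adjusted p = 0.315 with an estimated correlation). Of 14 Polycomb targets 1 rose and 1 fell (Hoxd8 and Hoxa7; camera adjusted p = 0.889).

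The remaining lists had 0 called genes in edgeR over all genes tested. Ribosomal proteins (68; Rpl23 0.10, Rplp1 0.14) had a camera adjusted p of 4.36e-09 upwards (adjusted p = 0.565 with an estimated correlation), with a median of 0.23 overall and 0.95 in Dam-CBX1 library 1. Ribosome biogenesis genes (28; Npm1 0.04, Wdr43 0.27) had a camera adjusted p of 0.000819 (adjusted p = 0.565 with an estimated correlation), and p53 genes (15; Mdm2 -0.07, Rrm2b -0.11) one of 0.0498 (adjusted p = 0.315 with an estimated correlation). Oocyte genes (36; Dppa3 0.17, Zbed3 -0.58), canonical imprinted genes (15; Cdkn1c -0.20, Igf2r 0.40), PRC2 and PRC1 genes (23; Suz12 -0.03, Bmi1 -0.11), lamina genes (16; Tpr 0.30, Tmpo -0.13), H3K9 genes (19; Trim28 0.01, Suv39h1 -0.03) and mitochondrial RNAs (15; mt-Cytb -0.17, mt-Nd1 -0.17) had none. Of 3 cumulus markers Nr5a2 (0.48) was higher and Tnfaip6 (-1.04) lower when adjusted over the list alone, and of 4 fibroblast markers Col1a1 (-1.57) was lower.

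Whether expression followed contacts was asked across genes and within units. Both comparisons used only genes that lay within 1 autosomal bin, which left 6264 of the 10793 genes tested in mKO embryos. Genes that span bins were left out, among them Sfmbt2, Gab1, Slc38a4, Jade1 and Smoc1. The 9 genes called up in mKO embryos that had a usable bin were too few for a test, as 0.224% of the other genes lay in a bin that gained contact. Among genes higher at an unadjusted p under 0.01, 1 of 67 lay in such a bin (1.49%) against 13 of 6197 others (0.210%; Fisher's exact p = 0.140, two-sided). In bins that lost contact lay 1 of these 67 (1.49%) against 2.28% of the others. Of 144 lower genes 0 lay in bins that gained contact. In bins that lost it lay 4 of the 144 (2.78%) against 2.25% of the others (Fisher's exact p = 0.570, two-sided). Across 6264 genes, which are not independent replicates, the changes of contact and expression had r = 0.0518 and rho = 0.0487. Within 9 units, cells with and without contact at a gene's bin were compared against shuffled cells. The observed minus shuffled log2 difference of expression was 0.00778 ± 0.0365, below 0 in 5 of 9 units (two-sided exact sign-flip p = 0.539). The stages lay on opposite sides, a split seen in the data and not tested: all 4 zygote units were below 0 (-0.0377 to -0.00861), and of the 5 2-cell and 8-cell units 4 were above 0 (0.0327 to 0.0662) and 1 was at -0.0115. Transcripts were not divided into those made in the oocyte and those made by the embryo. The 4 zygote units, which the pooled test includes, therefore cannot show whether contact affects transcription.

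The tethering experiment asked whether Polycomb-marked chromatin can be brought to the lamina. Embryos were injected with the lamina protein Lap2b fused to Cbx7(CD), as labelled, from the H3K27me3-reading protein Cbx7, or with Lap2b alone as control. K2 rose from 48.8% ± 4.44 in 6 Lap2b embryos to 80.1% ± 8.87 in 21 Cbx7-Lap2b embryos of the same library, a gain of 31.3 points (permutation p = 1e-05, adjusted p = 3e-05, two-sided). K4 rose from 37.0% ± 3.28 to 50.1% ± 6.46 (permutation p = 8e-05, adjusted p = 0.00016), K3 fell by 23.1 from 56.1% ± 3.67 to 33.0% ± 6.10 (permutation p = 1e-05, adjusted p = 3e-05) and K6 fell by 9.49 points to 9.49% (permutation p = 0.00022, adjusted p = 0.00033). K5 (-4.36, permutation p = 0.0473, adjusted p = 0.0568) and K1 (-0.782, permutation p = 0.635) did not pass. Over 3 units of each treatment K2 read 51.3% ± 2.65 and 75.1% ± 4.72, K3 53.1% ± 2.24 and 32.1% ± 0.611 and K4 37.0% and 47.0% ± 2.81, each with an exact p of 0.1, the smallest that 3 against 3 can give. K2 lay between 39.6% and 47.6% in uninjected 2-cell units.

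The same treatments read with untethered Dam in another library gave no such gain. K2 was 35.9% in 9 Lap2b and 32.2% in 17 Cbx7-Lap2b embryos, a difference of -3.70, and no cluster passed (lowest permutation p = 0.134). That library was non-hybrid, with a median per cell of 9364 counts for Lap2b and 11105 for Cbx7-Lap2b. The Dam-LMNB1 library was hybrid, with 40617 and 70672. Construct, library, cross and depth thus differed together between the 2 changes. The Dam-LMNB1 change exceeded the Dam-only change by 35.0 points in K2 (permutation adjusted p = 3e-05) and by 15.9 in K4 (permutation adjusted p = 0.00026), and lay below it by -25.1 in K3 (permutation adjusted p = 3e-05) and -11.2 in K6 (permutation adjusted p = 0.00195). Of the 10 loci, none passed in Cbx7-Lap2b embryos (lowest p 0.0169 at Jade1, permutation adjusted p = 0.0985).

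**Figure D3:**
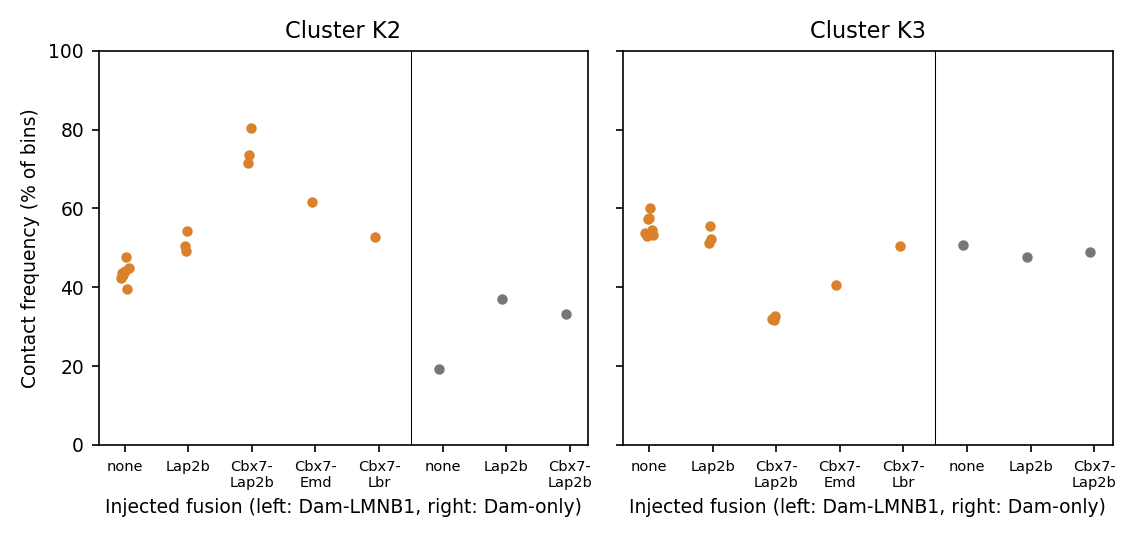
Contact frequency (% of cells in contact, averaged over bins, vertical axis, 0 to 100) of clusters K2 and K3 per unit of 2-cell embryos that were uninjected or injected with Lap2b, Cbx7-Lap2b, Cbx7-Emd or Cbx7-Lbr, read with Dam-LMNB1 (orange) or Dam-only (grey). The Dam-LMNB1 units of Cbx7-Lap2b average 75.1% in K2 against 51.3% for Lap2b, and 32.1% against 53.1% in K3.

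In counts, 4285 of 18912 bins changed, 2178 up and 2107 down (edgeR). K2 had 34.4% and K4 21.3% of bins up, and K3 had 31.6% and K6 16.0% down. On chromosome 11, 16 K4 bins from 55600001 to 57200000 rose with a peak log2 change of 2.56 (14.1 to 85.4 CPM, edgeR adjusted p = 0.000128). Chromosome 6 from 111800001 to 112400000 (2.74) and chromosome 7 from 77900001 to 78200000 (2.67, K4) rose as well. Chromosome 8 from 125400001 to 125500000 (-2.94), chromosome 7 from 66500001 to 66700000 (-2.58) and chromosome 14 from 118500001 to 118600000 (-2.58) fell. DESeq2 called 113 up and 115 down, and edgeR called 0 without the hybrid library that held both treatments and 2702 without the library that mixed Dam-only and Dam-LMNB1 cells.

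Transcripts did not change detectably with tethering. Among 10757 genes edgeR called 0, with 322 at an unadjusted p under 0.05, and DESeq2 called 0, with 44 at an unadjusted p under 0.05. Cbx7 read 14.8 to 21.3 CPM in the Lap2b units and 0 to 16.7 CPM in the Cbx7-Lap2b units (log2 change -0.42), with 1 unit at 0, and Tmpo 391 and 346 (-0.18), and whether the injected RNA is seen by these 3′ tags was not given in the sources used here. Emd (-0.21), Lbr (-0.15), Lmnb1 (0.03) and Eed (0.09) did not pass either. Removing the uninjected, Cbx7-Lap2b and Lap2b library gave 7 calls.

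No list had a gene called over all genes by edgeR. Of 21 ZGA genes 3 were higher when adjusted over the list alone (Gm5662 0.87, Usp17lc 0.83, Gm8300 0.56; the most expressed, Sp110 and Zfp352, had -0.08 and 0.25; camera adjusted p = 7.04e-07), and of 36 oocyte genes 4 (Obox5 0.46, Zbed3 0.45, Oosp3 0.43, Tcl1 0.39; camera adjusted p = 0.000105). Camera also put the 68 ribosomal protein genes (Rpl23 -0.03; adjusted p = 2.05e-10) and the 28 ribosome biogenesis genes (Npm1 -0.11, Wdr43 -0.15; adjusted p = 0.00249) lower, and with an estimated correlation the adjusted p of all lists lay between 0.852 and 0.904. None was called, over all genes or adjusted over the list alone, among 21 lineage genes (Klf17 -0.12, Gata4 -0.23), 8 noncanonical (Jade1 0.17, Xist 0.09) and 18 canonical imprinted genes (Phlda2 -0.15, Igf2r -0.35), 14 Polycomb targets (Hoxa7 0.15), 23 PRC2 and PRC1 genes (Suz12 0.14, Bmi1 0.22), 16 lamina (Tpr -0.05), 19 H3K9 (Trim28 -0.03, Suv39h1 0.07) and 14 p53 genes (Mdm2 0.04, Rrm2b 0.05), 4 cumulus (Nr5a2 -0.09, Amhr2 -0.08) and 4 fibroblast markers (Fn1 0.01, Sparc 0.48) and 15 mitochondrial RNAs (mt-Cytb 0.09, mt-Nd2 0.04).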

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

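The tests of sire strain, accessibility to Dam, developmental timing and single libraries, and all counts over other splits of the samples, were chosen only after the result was seen, and the tests on cells matched for depth were set before theirs.

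The parental difference at the lamina in Eed mKO embryos stood out because it changed sign in K4 (16.6 to -7.23) and K5 (6.22 to -5.38) and shrank in K1 (-14.3 to -4.20), and because the change differed between the alleles, by -23.3 points in K4, -11.4 in K5, -5.54 in K2 and 11.3 in K1. Depth was argued against for K4: among 42 pairs of cells matched within libraries the change was still -21.0 (permutation p = 1e-05, the smallest possible). The sire strain cannot be told apart from genotype here, because the growth protocol names PWK/PhJ fathers for controls and JF1/MsJ for mKO embryos and the variants used to assign control reads are not given in the sources used here. The paternal share of transcripts of embryonic genes, which could fall in controls if their fathers lacked the JF1 variants, differed by a mean of -0.0970 points between genotypes (-3.46 to 3.30, higher in 2 of 5 libraries, exact sign-flip p = 0.8125, two-sided), and that of DamID counts, which contacts themselves can move, was not lower in controls (47.4%, 50.0% and 48.0%) than in mKO units (46.5%, 40.1% and 47.6%) of libraries 1 to 3. Loss of maternal Eed, the difference the design names, stays open as well and may be the source of the pattern.

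With Cbx7-Lap2b, K2 gained lamina contacts by 35.0 points more than in Dam-only cells, K4 by 15.9 more, while K3 and K6 lay -25.1 and -11.2 below. A change in accessibility to Dam was argued against in the Dam-only library alone, where the K2 change was -3.70 points. That library differed in cross and depth from the Dam-LMNB1 hybrid library, in which accessibility was not read. A difference in depth was argued against too: Lap2b cells had a median of 40617 counts and Cbx7-Lap2b cells 70672, and among 10 pairs of matched cells K2 still rose by 27.4 points (permutation p = 0.00067). Tethering of H3K27me3 chromatin by the fusion may account for the gain, as a hypothesis that rests on 1 library for the embryo test and on 3 units per treatment.

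As a list, ZGA genes were lower in Eed mKO embryos by camera with its preset correlation, though 0 of 23 were called in edgeR over all genes (15 at an adjusted p over the list alone) and adjusted p = 0.315 with an estimated correlation. A single library as the source was argued against, because the highest of the 5 library medians was -0.0835 (exact sign-flip p = 0.0625, the smallest possible with 5). A difference in timing cannot be told apart: across 5624 genes the mKO change correlated with the 2-cell to 8-cell change at r = 0.163 (rho = 0.185), above 0 in 4 of 5 libraries (-0.138 to 0.220, exact p = 0.312). It also correlated with the zygote to 2-cell change (r = 0.140, rho = 0.165, above 0 in 2 of 5 libraries, exact p = 0.75), at which ZGA genes mostly rose. Loss of maternal Eed or a small difference in age may each lie behind it, and the sire strain cannot be told apart from genotype here either.

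Zygote library 1 had a K4 contact frequency of 14.3% (48 cells), far from the 16.6% to 17.2% of the other zygote units. Ribosomal protein genes had a median log2 change of 0.95 in Dam-CBX1 Eed library 1 and -0.03 to 0.21 in the others. These were 2 of 33 groups of samples examined, and chance singles out about 1 in 20.

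Chance was argued against for the 4 stage counts, where the real split was the 1 of 25 drawn with as many calls. That is the smallest share 25 splits can give. Stages lay mostly in separate libraries, so these splits cannot tell stage from library. For genes, 8676 calls stood against a highest other of 0 for the zygote to 2-cell step and 6566 against 2996 for the 2-cell to 8-cell step. For bins, 12108 stood against 3886 and 5539 against 207. For Eed genes chance could not be excluded. There 3 of 40 splits gave at least the 29 calls, but most of these splits cannot speak for chance. With library as a block, a library that a split does not part adds nothing to the contrast. A parted library is divided into its real genotypes. The split with 358 calls parted 1 library alone, so it was the genotype contrast of that library. Among the 16 splits that part every library, too few for a share under 0.05, the highest other was 0. Splits were also too few for Eed bins, with 2009 calls against a highest other of 0 in 10 splits and in the 4 that part every library, for Cbx7-Lap2b bins, with 4285 against 0 in 10, and for Cbx7-Lap2b genes, where all 10 splits reached the real count of 0 and the highest gave 133.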

How the results depend on the processing

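Alternatives on units of more than 10 cells, whole-embryo wells, all cells in place of the allelic filter and unmodified-Eed units, also averaged per library, were tests chosen only after the result was seen. Of 650 alternatives to 76 results, 540 were kept and 110 were not. A tested difference was kept if its direction and side of the threshold held. Counts of genes or bins were kept within a fixed ratio of the main count, whatever their balance of up and down. Correlations of constructs were kept within a tolerance, and the overlap of Eed genes and bins by side of the threshold alone. The minimum of 10000 counts removed no cell in 38 of 60 cases, and 502 were kept without those. Of 399 fits that left out a library, 360 were kept. The cause was not tested unless stated. At 2-fold the simulated stage fits found 25% and 14% of genes and the Eed bin fit 29% of bins, so small changes were often not detectable at these depths and numbers of units.

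DESeq2 called 228 bins for Cbx7-Lap2b, 53 genes and 23 bins for Eed mKO and 3592 bins between the 2-cell and 8-cell stages. Eed mKO genes numbered 66 with Dam-LMNB1 libraries alone and 180 with embryos as replicates. Without an expression filter 14475 genes were called between zygote and 2-cell stage, 195 for Eed mKO and 1 for Cbx7-Lap2b. With no library block Eed mKO had 0 genes and 368 bins and Cbx7-Lap2b 0 genes, and no other result was run without the block. Thinned cells gave a 2-cell to 8-cell similarity change of -0.0221, and non-hybrid crosses gave -0.117 (adjusted p = 0.0571) and -0.0104 for the 2 steps. Without division by Dam-only the correlations of Dam-LMNB1 were 0.195 with Dam-2E12 and 0.0416 with Dam-CBX1, and a pseudocount of 10 gave 0.489 for Dam-2E12 with Dam-CBX1. With at least 10000 counts the Eed mKO K1 change was 2.67 (adjusted p = 0.0429).

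All cells gave a paternal excess of 10.9 in K2 (adjusted p = 0.0479), maternal Eed mKO changes of -4.95 in K1 and -1.48 in K5, and a change of paternal excess of 2.83 in K3. Unmodified-Eed units gave an excess of 18.8, 1.08, 20.3 and 8.94 in K2 to K5, and averaged per library 0.386 in K3 with adjusted p = 0.0729 in K2, K4 and K5. Shares of counts gave K1 -4.83 at the first stage step and K1 -2.74, K4 0.853 and K5 -0.0520 at the second. For the paternal excess they gave K1 -5.63, K2 4.79, K3 -2.24 and K6 -0.880, and for Cbx7-Lap2b K1 -3.23, K5 0.0623, K6 -1.33 and, over units, K5 0.00283. For Eed mKO they gave K1 2.82 and changes of the paternal excess of 3.45 in K3 and 1.16 in K6. Units of more than 10 cells gave K1 5.65 and K6 5.24 at the first step, and K1 -3.04, K5 -3.76, all bins -0.639 and similarity -0.0245 at the second.

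With libraries as replicates no p can pass, by construction. The Eed mKO changes were then 20.7, -13.2, 6.47, -7.91 and -14.5 for K2 to K6. On the maternal genome they were 2.50 (reversed), 20.3, -7.52, 16.3, -0.432 (reversed) and -9.96 for K1 to K6, on the paternal genome 10.0, 8.71, -8.77, -9.07, -13.8 and -11.7, and for the paternal excess 7.54, -11.6, -1.25 (reversed), -25.4, -13.3 and -1.73 (reversed).

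Leaving out each library gave 0 to 42 Eed mKO genes, 0 to 7 Cbx7-Lap2b genes, 3503 to 5800 bins between 2-cell and 8-cell stage, 18 to 3406 Eed mKO bins and 0 to 4856 Cbx7-Lap2b bins. Similarity ranged from -0.114 to -0.0840 at the first stage step and from -0.00837 to 0.0173 at the second. At the first step K1 ranged from 2.94 to 5.35 and K6 from 4.38 to 6.42, and at the second K1 from -1.16 to 2.25. Eed mKO K1 ranged from 1.32 to 4.18. The maternal changes ranged from -4.23 to 7.69 in K1, -13.0 to -3.27 in K3, -0.224 to 1.26 in K5 and -11.3 to -7.74 in K6, and the paternal ones from 10.2 to 11.3 in K2, -9.15 to -7.14 in K3, -7.47 to -6.49 in K4 and -10.5 to -9.78 in K6. Changes of the paternal excess ranged from 4.34 to 12.5 in K1, -3.87 to 3.86 in K3 and -2.49 to 0.802 in K6. The paternal excess itself ranged from -2.63 to 0.225 in K3 and from -1.03 to 1.41 in K6.

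Not run were the alternatives for Dam-CBX1 bins, where 1 library alone held both genotypes, Cbx7-Lap2b bins with a block, and leaving out a library in the embryo test of Cbx7-Lap2b, since 1 library alone held contact cells of both treatments; the plan had assumed 2.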

Other observations

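The test of sister cells, the share of maternal transcripts and the comparison of Dam-CBX1 shares were tests chosen only after the result was seen.

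Several noncanonical imprinted genes, known for paternal expression in early embryos, had a higher share of maternal transcripts in Eed mKO than in control embryos. For Jade1 18 of 132 allele-assigned transcripts were maternal in controls (13.6%) and 66.3% in mKO embryos, higher in 5 of 5 libraries (exact sign-flip p = 0.0625, the smallest possible, two-sided). Gab1 went from 3.13% to 15.7% (3 of 3 libraries, exact p = 0.25), Tle3 from 15.5% to 32.3% (4 of 4, exact p = 0.125) and Enc1 from 28.1% to 46.2% (2 of 2). Sfmbt2 had 0 of 15 maternal transcripts in controls (95% Wilson upper limit 20.4%) and 7 of 15 in mKO embryos. Runx1 had 0 of 11 and 4 of 14, Platr20 1 of 10 and 7 of 10, and Xist 1 of 8 and 5 of 11. Others on the list had few counts, such as Slc38a4 (2 of 8 and 3 of 8). Among them Bbx read 71.4% in controls (15 maternal and 6 paternal) and 81.5% in mKO embryos. Rbms1 read 66.7% (4 and 2) and 90.9%, and Sh3gl3 71.4% (5 and 2) and 76.5%. The 95% Wilson intervals of these controls were 50.0 to 86.2, 30.0 to 90.3 and 35.9 to 91.8. A maternal excess in controls is thus not shown for Rbms1 and Sh3gl3. Gpd2, not on that list, went from 55.3% to 76.4% (3 of 4, exact p = 0.375). None passed 0.05 over libraries, and the doubt on the sire strain of controls applies to each value. Maternal transcripts were not divided into those made in the oocyte and those made by the embryo. A higher maternal share thus does not show that the maternal allele was transcribed in the embryo.

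Dam-CBX1 signal was compared in the 1 library with cells of both genotypes, 5 control and 11 mKO, so no test was made. The K2 share of counts was 18.0% (95% Wilson interval 17.6 to 18.4) in controls and 13.3% (13.1 to 13.6) in mKO cells, and K4 had 10.0% (9.70 to 10.4) and 6.53% (6.33 to 6.73). K3 went from 15.6% to 18.9%, K6 from 23.3% to 26.4% and K1 from 13.8% to 15.7%. In unmodified embryos Dam-only held 11.1% in K2, 7.34% in K4, 17.8% in K3, 27.1% in K6 and 16.6% in K1. In each of these clusters the mKO share lay nearer to Dam-only than the control share did. A weaker Dam-CBX1 signal over background thus cannot be told apart from a change of H3K9me3. The median count per cell was 6122 in controls and 4659 in mKO cells.

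Fusions of Cbx7(CD) to other nuclear envelope proteins were read in 1 library each. K2 stood at 61.7% and K3 at 40.7% with Cbx7-Emd (17 cells), and at 52.7% and 50.5% with Cbx7-Lbr (22 cells). Cbx7-Lap2b in the same library had 73.5% and 31.7% (16 cells). Dam-only in 40 uninjected cells marked K2 at 19.3%, K3 at 50.7% and K6 at 75.1%.

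Contacts at loci varied by stage without a test. Hoxd was contacted in 21.8% of zygote, 66.7% ± 16.9 of 2-cell and 39.2% of 8-cell cells (4, 6 and 4 units), Hoxc in 11.9%, 29.3% and 17.5%, Sfmbt2 in 9.72%, 16.8% and 7.31%, and Jade1 in 36.7%, 22.3% and 25.3%.

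Cells of 1 embryo resembled each other in their contacts more than cells of different embryos of the same unit. At the 2-cell stage the mean phi was 0.376 over 59 sister pairs and 0.286 over 2024 other pairs (permutation p = 0.0001, the smallest possible), and at the 8-cell stage 0.331 over 440 and 0.265 over 4622 pairs (permutation p = 0.0001). These means pool pairs over units, and permuting cells among embryos within units gave mean differences of 0.00970 and 0.0163, the part due to which units the pairs came from. Differences between libraries as the whole source were argued against, since the lowest 2-cell unit still had a difference of 0.0430, and the lowest 8-cell unit 0.0380. Contacts may be shared by descent, as a hypothesis, and a dose of the injected construct common to an embryo stays open.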
